A study of Mus musculus with 17 samples.

How the data were processed

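Total RNA of 17 mouse livers was measured by sequencing after depletion of ribosomal RNA with a stranded kit, per the labels' protocols. The labels give the tissue as liver, the cell type as hepatocyte and the age as 8 weeks. The 4 groups are WT mice from WT ancestors (n = 4), Khdc3-null (KO) mice from KO ancestors (n = 3), and 2 groups bred from heterozygous parents with both WT and KO grandparents: genetically WT mice (WT_star, n = 4) and genetically KO mice (KO_star, n = 6). Libraries are named by group and the number in their title. No number occurs in more than 1 group, so no libraries were paired. The labels give no litter, batch, date or strain, and nothing says that the mice of a group came from separate litters, so p-values measure only the spread between these samples.

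The authors deposited 1 table of 27020 genes with a normalized value per library, and the submitters' processing notes name cutadapt, HISAT2, DESeq2 and the build GRCm38 without versions. The counting tool, the gene annotation, the strand setting and any filter are not given in the sources used here. The deposited values are a signal of gene reads divided by 1 size factor per library, as every value in a column is a whole multiple of what 1 read is worth there. With a tolerance of 0.001 reads, 100.0% of the values came out as whole reads. The value of 1 read lay between 0.792 and 1.182, and the libraries held 17.62 to 26.7 M (mega) reads in genes. A floor of 3 reads corresponds to 2.38 to 3.55 in deposited values. The reads carry no molecular identifiers, so floors and intervals cover counting error only. Of the gene identifiers, 26963 matched GENCODE release M21, 24354 of them with the version number, and positions are given on GRCm38 from that annotation. Reads of near-identical copies, such as the H2 and Cyp2c families or the pseudogene copies of Rps2, Eif3j2 and Atp6v0c, may be divided between them by the authors' counting, and with no strand setting stated a gene cannot be separated from an antisense partner.

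Replicates were compared before averaging. Over genes with at least 20 reads, all 30 pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 8.53 to 101.68, so each library was counted as 1 sample.

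The values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, in 1 model with a mean per group over all 17 libraries and a trended, robust variance (statmod 1.5.0). Genes with a value of at least 10 in at least 3 libraries were kept, which left 16157. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes and their standard errors (SE) are on the log2(value + 1) scale, which understates the change of low genes, and a fold is that difference taken out of the log. The contrasts were KO against WT, WT_star against WT, KO_star against WT_star, KO_star against KO, KO_star against WT, and the interaction of genotype and ancestry, which is KO_star minus WT_star less KO minus WT. Means of deposited values are given with their SD and n.

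Contrasts with a group in common share its chance values. For these, 100 draws reassigned the residuals of the 17 libraries with no group effect, the overlap of independent lists was computed, and the WT libraries were split into pairs used in 1 contrast each. Genes are not independent replicates, so no p was computed over genes for a correlation of fold changes.

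The design, the alternatives, the rule for named genes and 44 gene lists of liver metabolism, stress, immunity, growth and cell types were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which left 40, with adjustment over these lists. Camera with an estimated correlation and fry, in its directional and its mixed test, were run beside it. Members were counted as changed by the adjustment over all genes and adjusted over the list alone. Adipocyte markers (1 of 7 tested), pancreatic acinar markers (1 of 12), subcortical maternal complex and oocyte genes (2 of 13) and sex check genes (1 of 5) had too few expressed members for a set test. Named genes are, per contrast, the 10 higher and 10 lower with the largest change among those past the threshold with a mean of at least 100 in the higher group and no overlap between the libraries compared, up to 4 changed members of each list that was called or had several changed members, up to 10 genes changed the same way in KO against WT and WT_star against WT, and, where fewer than 5 genes passed, the 5 with the smallest p. Predicted genes, pseudogenes named as such and genes without a symbol were left out by that rule. Some genes that it named are not reported here.

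The alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, quantile normalization, equal library totals, library weights, only the libraries of the groups compared, a minimum log2 fold change of 1, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The pipeline was tested on simulated data, 1 contrast at a time, over 16157 genes. For KO against WT it recovered 32.8%, 53.7% and 81.8% of genes changed by 1.5, 2 and 4 times. The shares were 28.4%, 56.7% and 81.8% for WT_star against WT, 46.3%, 71.6% and 93.9% for KO_star against WT_star, and 40.3%, 64.2% and 80.3% for KO_star against KO. Between 2.6% and 4.7% of the simulated calls were false. The simulated genes were independent, each with 1 relative spread for all groups. In the data the spread could differ between groups, as for Rps2 (SD 42.61 in WT and 793.9 in WT_star), so these shares may not carry over. Tests of gene positions compared the changed genes with 10000 sets matched for level and with 10000 shuffles of positions. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.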

Results

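Liver RNA of 17 mice at 8 weeks of age was compared between WT and Khdc3-null mice of pure ancestry and WT_star and KO_star mice of mixed ancestry. Each library held 17.62 to 26.7 M reads in genes. The X-linked RNA Xist had 25243 to 35961 reads in every library and the Y-linked gene Kdm5d 0 or 1. Albumin took 9.68% ± 0.47 (SD, n = 4) of the reads in WT, 6.72% ± 0.35 (n = 3) in KO, 7.69% ± 0.63 (n = 4) in WT_star and 9.15% ± 1.03 (n = 6) in KO_star.

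Khdc3, a gene of the oocyte's subcortical maternal complex on chromosome 9 at 73101836 to 73104438, was close to absent from liver in all groups. It had 3 reads in the 4 WT libraries together (0.0334 per M reads, exact 95% Poisson interval 0.00688 to 0.0975), 7 in the 3 KO libraries (0.113, 0.0454 to 0.233), 4 in the WT_star libraries (0.0485, 0.0132 to 0.124) and 7 in the KO_star libraries (0.055, 0.0221 to 0.113). No library had more than 4 reads, so Khdc3 fell below the filter and was not tested between genotypes. The level of Khdc3 in liver therefore does not check the genotype labels.

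KO against WT asks what differs in the liver of Khdc3-null mice with Khdc3-null ancestors. By camera, KO livers had higher RNA of fatty acid oxidation, lipid droplet, interferon and antigen presentation genes, and lower RNA of urea cycle and cell division genes. No list was called with an estimated correlation (smallest adjusted p = 0.492), and no cell division gene passed by the adjustment over all genes. The steroid hydroxylase gene Cyp17a1 (chromosome 19 at 46667165 to 46673172) was at 1191 ± 742 (SD, n = 3) in KO and 67.4 ± 12.7 (n = 4) in WT, a log2 fold change of 3.95 (SE 0.48, adjusted p = 0.00057). The cytochrome P450 gene Cyp2c39 (chromosome 19 at 39510862 to 39568529) fell from 17560 ± 4817 (n = 4) to 224.3 ± 42.4 (n = 3), a log2 fold change of -6.26 (SE 1.01, adjusted p = 0.0057). Of 16157 genes tested, 467 changed, 213 higher and 254 lower in KO, and 2697 had an unadjusted p under 0.05.

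Among the genes with the largest rise, Wdr72 lies on chromosome 9 at 74110356 to 74283308, 1.01 Mb from Khdc3. It was at 672.9 ± 160.9 (SD, n = 3) in KO and 3.298 ± 2.03 (n = 4) in WT (log2 fold change 7.37 on the log2(value + 1) scale, adjusted p = 0.011). Them7 rose with a log2 fold change of 4.82 (SE 0.39, adjusted p = 1.7e-06). The phosphatidylcholine transfer protein gene Pctp (4.77), the Rac activator gene Tiam2 (4.56) and the ribosomal protein gene Rps2 (3.83) also rose, with adjusted p of 0.032, 0.019 and 0.026. Csad, whose enzyme makes a taurine precursor, rose from 1028 ± 154.1 (n = 4) to 7311 ± 1155 (n = 3), with an adjusted p of 0.033. Cdcp1 (3.02) and the non-coding AI506816 (2.80) rose with adjusted p of 0.012 and 0.0032. Among the genes that fell, the neighbouring basement membrane collagen genes Col4a3 (-5.75) and Col4a4 (-3.30) had adjusted p of 0.00084 and 0.00057. The prominin genes Prom2 (-6.85) and Prom1 (-2.36) lie on different chromosomes and fell with adjusted p of 0.026 and 0.042. Lipoprotein lipase, Lpl, fell from 3601 ± 2038 (n = 4) to 333.4 ± 54.8 (n = 3), with an adjusted p of 0.026. Aph1c of the gamma-secretase complex (-3.65), the class I gene H2-Q1 (-3.62), the initiation factor gene Eif3j2 (-2.95) and the phosphoinositide phosphatase gene Synj2 (-2.39) fell with adjusted p of 0.0073, 0.035, 0.021 and 1e-04. Like Wdr72, Aph1c lies near Khdc3 on chromosome 9, at a distance of 6.29 Mb. For every gene named in this contrast, the libraries of KO and WT did not overlap, which the naming rule required of the genes with the largest change. Over all genes, the libraries did not overlap for 2966, 18.4% of those tested, where chance gives 5.71%.

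Camera called 16 of the 40 lists in KO against WT, 6 higher and 10 lower. With an estimated correlation none was called, and the smallest adjusted p was 0.492. The directional test of fry called none, and its mixed test, which takes changes in either direction, called 17. Fatty acid oxidation and ketogenesis had a median log2 fold change of 0.39 over 34 genes (adjusted p = 7.38e-07, and 0.582 with an estimated correlation). Of these, 3 rose by the adjustment over all genes and 8 adjusted over the list alone, among them the peroxisomal gene Ehhadh (1.09, adjusted p = 0.012) and the carnitine acetyltransferase gene Crat (672.9 ± 142.8 in WT, n = 4, and 1330 ± 155.1 in KO, n = 3, adjusted p = 0.043). Lipid droplet genes had a median of 0.26 over 14 (adjusted p = 0.0104, and 0.582 with an estimated correlation). The fatty acid transporter gene Cd36 (1.06), the lipase inhibitor gene G0s2 (1.82) and the droplet coat gene Plin2 (0.68) rose with adjusted p of 0.0049, 0.046 and 0.018, and 4 members rose adjusted over the list alone. Interferon response genes had a median of 0.41 over 36 (adjusted p = 3.07e-06, and 0.582 with an estimated correlation), with 3 changed by the adjustment over all genes and 10 adjusted over the list alone. In this list WT 25 had a mean level of 7.452, against 6.754 to 6.968 in the other WT libraries and 7.364 to 7.554 in KO. Ifi44 (1.29), Mx2 (0.64) and the signal transducer gene Stat2 (0.47) rose with adjusted p of 0.037, 0.038 and 0.032.

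Antigen presentation genes had a median log2 fold change of 0.56 over 18 (adjusted p = 0.00278, and 0.582 with an estimated correlation). The class II gene H2-Eb1 (4.52, adjusted p = 0.034) and the class I genes H2-K1 (1.01, adjusted p = 0.0076) and H2-Q10 (0.80, adjusted p = 0.021) rose, while adjusted over the list alone 6 rose and 3 fell. H2-Eb1, H2-K1 and H2-Q10 lie in 1 segment of chromosome 17 (30584936 to 35470089), where 11 of 145 tested genes changed and H2-Q1 fell. They may not be independent changes, which the preset correlation of 0.01 nearly takes them to be. Heat shock genes had a median of 0.44 over 14 (adjusted p = 0.000735, and 0.582 with an estimated correlation), and the small heat shock protein gene Hspb1 (2.94, adjusted p = 0.00082) was the 1 member that passed, by both adjustments. B cell and plasma cell markers had a median of 0.58 over 9 (adjusted p = 0.00235, and 0.582 with an estimated correlation), and the antibody chain gene Igkc rose by both adjustments, from 23.41 ± 6.01 (n = 4) to 67.43 ± 13.4 (n = 3), with an adjusted p of 0.014. The mean level of these markers in WT 26 was 4.279, within the 4.22 to 4.374 of the KO libraries.

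Among the lower lists, urea cycle and amino acid breakdown had a median of -0.27 over 26 genes (adjusted p = 1.85e-06, and 0.492 with an estimated correlation), with 4 members lower by the adjustment over all genes and 7 adjusted over the list alone. Carbamoyl phosphate synthetase, Cps1, fell from 125400 ± 9370 (SD, n = 4) to 87270 ± 12780 (n = 3), with an adjusted p of 0.018. Arg1 (-0.39), Agxt (-0.59) and Otc (-0.29) fell with adjusted p of 0.028, 0.038 and 0.048. Cell proliferation genes had a median of -1.25 over 29 (adjusted p = 1.88e-10, and 0.582 with an estimated correlation). None of them passed by the adjustment over all genes, where limma was the tool, and 10 fell adjusted over the list alone. In this list library WT 26 had a mean level of 5.567, against 6.809 to 7.047 in the other WT libraries and 5.282 to 5.526 in KO. DNA methylation enzymes had a median of -0.32 over 10 (adjusted p = 0.0143, and 0.492 with an estimated correlation), and Dnmt3a fell (-0.52, adjusted p = 0.025), with 2 members lower adjusted over the list alone. Stellate cell and fibroblast markers had a median of -0.33 over 15 (adjusted p = 0.0143, and 0.582 with an estimated correlation), and Pdgfrb fell (-0.56, adjusted p = 0.049), with 4 members lower adjusted over the list alone. Immediate early genes (-0.57, adjusted p = 0.0211, and 0.608 with an estimated correlation) had no changed member by either adjustment.

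The calls of 5 further lower lists were lost without any 1 of several libraries of both groups, and leaving out a library also lowers n. Gluconeogenesis and fasting (median -0.29, adjusted p = 0.0211, and 0.582 with an estimated correlation) was not called without WT 27, WT 28 or KO 30 (adjusted p up to 0.0834) and had no changed member by either adjustment. Glycolysis, fructose and glycogen (-0.06, adjusted p = 0.0478, and 0.608 with an estimated correlation) was not called without WT 26, WT 27, WT 28 or KO 30 (up to 0.205), and had 0 changed members over all genes and 1 adjusted over the list alone. Nuclear oxidative phosphorylation (-0.07, adjusted p = 0.0478, and 0.907 with an estimated correlation), with Ndufb8 lower by both adjustments (-0.39, adjusted p = 0.035), was not called without WT 26, WT 28, KO 30 or KO 32 (up to 0.259). Cytosolic ribosomal proteins (median -0.05, mean 0.01, adjusted p = 0.0346, and 0.907 with an estimated correlation) were not called without WT 26, WT 28 or KO 32 (up to 0.383), and their 1 changed member by both adjustments, Rps2, rose. Periportal hepatocyte markers (-0.32, adjusted p = 0.0284, and 0.492 with an estimated correlation) were not called without WT 26 or KO 30 (up to 0.0778), and had 0 changed members over all genes and 1 adjusted over the list alone. Outside the called lists, the bile acid hydroxylase gene Cyp2c70 (-0.85, adjusted p = 0.0036) and the sterol transporter gene Abcg5 (-0.59, adjusted p = 0.047) fell, the phospholipid transfer gene Pltp rose (0.64, adjusted p = 0.026) and the transporter gene Slc22a29 fell (-1.79, adjusted p = 0.034).

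The number of changed genes depended on the tool and on single libraries. It was 438 by edgeR, 865 by DESeq2, 1280 with library weights and 754 with only these 7 libraries, and 282, 232, 177, 150 and 168 without WT 27, WT 28, KO 30, KO 31 or KO 32. With equal library totals 338 genes were higher and 188 lower. Them7, Cyp17a1, Hspb1, AI506816, Kdm2b, As3mt, Cd36, H2-K1, Cyp2c70, Fut10, Arhgef10, Synj2, Col4a4, Col4a3, Aph1c and Cyp2c39 kept their call in every alternative in which they were tested, left-out libraries included, other than the minimum log2 fold change of 1, which Cyp2c70 (-0.85) does not reach. Each other gene named in this contrast lost it in at least 1 of them, with adjusted p of up to 0.2.

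WT_star against WT asks what differs in mice that are genetically WT but have KO grandparents. The same Cyp17a1 and Them7 genes that were high in KO were high in WT_star, and Cyp2c39 and the exchange factor gene Arhgef10 were lower. Interferon response genes and B cell markers were higher by camera, and no list was called with an estimated correlation (smallest adjusted p = 0.825). Cyp17a1 was at 2082 ± 989 (SD, n = 4) in WT_star against 67.4 ± 12.7 (n = 4) in WT, a log2 fold change of 4.82 (SE 0.44, adjusted p = 7.9e-05). In WT_star, 146 genes changed, 86 higher and 60 lower, and 2414 had an unadjusted p under 0.05. Libraries did not overlap for 1446 genes, 8.9% of those tested, where chance gives 2.86%.

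Them7 rose with a log2 fold change of 3.75 (SE 0.36, adjusted p = 2.7e-05). The arsenic methyltransferase gene As3mt rose from 305.8 ± 23.7 (SD, n = 4) to 800.4 ± 121.5 (n = 4), with an adjusted p of 2.2e-05. AI506816 (3.20), the lysyl oxidase family gene Loxl4 (3.79) and Cdcp1 (2.77) rose with adjusted p of 0.0017, 0.045 and 0.027. The integrin gene Itga6 (1.66), the nebulin gene Neb (1.47), Spsb4 (1.26), the ciliary transport gene Ift81 (1.19) and the histone demethylase gene Kdm2b (1.19) rose with adjusted p of 0.017, 0.043, 0.016, 0.0014 and 0.0022. Arhgef10 fell from 430.4 ± 55.6 (n = 4) to 103.1 ± 16.4 (n = 4), with an adjusted p of 0.0031. The amino acid transporter gene Slc38a2 (-1.26), the thiopurine methyltransferase gene Tpmt (-0.96), the fucosyltransferase gene Fut10 (-1.44) and the neprilysin gene Mme (-1.53) fell with adjusted p of 0.0022, 0.023, 0.027 and 0.045. The steroid dehydrogenase gene Hsd17b6 (-1.27), Adgrv1 (-1.06) and Exd1 (-0.98) fell with adjusted p of 0.047, 0.034 and 0.043. Cyp2c39 fell with a log2 fold change of -5.21 (SE 0.93, adjusted p = 0.022), but library WT_star 21 was at 7421 while the other WT_star libraries were at 292 or less. The libraries of the groups did not overlap for any gene named in this contrast except Bhmt, as the naming rule required of the genes with the largest change.

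Camera called 11 of the 40 lists in WT_star against WT, 7 higher and 4 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.825, or by the directional test of fry, and the mixed test of fry called 9. Interferon response genes had a median log2 fold change of 0.57 over 36 (adjusted p = 1.22e-13, and 0.825 with an estimated correlation), and kept the call without each library. Ifih1 (0.51), the antiviral GTPase gene Irgm1 (0.58) and Ifi44 (1.43) rose with adjusted p of 0.018, 0.027 and 0.029, and 21 members rose adjusted over the list alone. B cell and plasma cell markers had a median of 0.50 over 9 (adjusted p = 0.00162, and 0.944 with an estimated correlation), with the antibody chain gene Ighm higher (0.85, adjusted p = 0.047) and 4 members higher adjusted over the list alone. The mean level of these markers in WT 26 was 4.279, above WT_star 20 (3.761), WT_star 21 (4.21) and WT_star 34 (4.069), and only WT_star 33 (4.923) was higher. Methionine and one-carbon metabolism had a median of 0.12 over 19 (adjusted p = 0.0181, and 0.825 with an estimated correlation), with Bhmt higher (0.92, adjusted p = 0.045) and 4 members adjusted over the list alone. It was not called without WT_star 34 (adjusted p = 0.0657). Urea cycle and amino acid breakdown had a median of 0.15 over 26 (adjusted p = 0.019, and 0.944 with an estimated correlation), with the glycine cleavage gene Gldc higher (0.61, adjusted p = 0.047) and 2 members adjusted over the list alone. It was not called without WT 27 or WT_star 34 (up to 0.104).

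The other calls of this contrast each had no changed member over all genes by limma and were lost without some single library. Antigen presentation genes (0.34, adjusted p = 0.0439, and 0.944 with an estimated correlation; 5 members higher adjusted over the list alone) and macrophage markers (0.27, adjusted p = 0.0439, and 0.944 with an estimated correlation; 0 members) were not called without WT 27, WT 28, WT_star 33 or WT_star 34, with adjusted p up to 0.36 and 0.837. Without each of the same libraries, neutrophil and monocyte markers (0.49, adjusted p = 0.0499, and 0.944 with an estimated correlation, up to 0.284) were not called. They had 1 member, Ngp, higher adjusted over the list alone. Lower were fatty acid oxidation (-0.17, adjusted p = 0.00432, and 0.944 with an estimated correlation), lost without WT 26, WT_star 33 or WT_star 34 (up to 0.284), and proliferation (-0.41, adjusted p = 0.0134, and 0.944 with an estimated correlation), lost without WT 25, WT 27, WT 28 or WT_star 34 (up to 0.103). Immediate early genes (-0.44, adjusted p = 0.0191, and 0.944 with an estimated correlation) were not called without WT 27 or WT_star 21 (up to 0.0825), and stellate cell markers (-0.14, adjusted p = 0.0439, and 0.944 with an estimated correlation) without WT 25, WT 27, WT_star 21 or WT_star 33 (up to 0.116). These 4 lower lists had 0 members changed adjusted over the list alone. Library WT_star 33 had the highest mean level of 9.611 for macrophage markers, against 8.368 to 9.091 in the other WT_star libraries.

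The number of changed genes was 109 by edgeR, 602 by DESeq2, 757 with library weights and 96 with only these 8 libraries, and 33, 41, 42, 33 and 57 without WT 26, WT 27, WT 28, WT_star 20 or WT_star 21. With equal library totals 107 genes were higher and 41 lower. Cyp17a1, Them7, AI506816, As3mt, Ift81, Kdm2b, Slc38a2 and Arhgef10 kept their call in every alternative, and each other gene named lost it in at least 1, with adjusted p of up to 0.16.

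WT_star and KO livers shared changed genes against WT. Cyp17a1, Them7, AI506816, Cdcp1, Kdm2b, As3mt and Spsb4 rose in both contrasts, and Arhgef10, Fut10 and Cyp2c39 fell in both. In all, 62 genes changed in the same direction, 47 higher and 15 lower, and 0 in opposite directions by limma. Independent lists would share 2.08 in the same direction, a value that leaves out the shared WT libraries. The 100 draws with no group effect shared 0, but they called a median of 0 genes in each contrast (at most 12 and 1), so their count does not measure what shared WT libraries add to the 62. Across genes, the fold changes of both contrasts correlated with r = 0.579, where the draws gave 0.466 on average (0.092 to 0.725). Their covariance was 0.1338 against 0.0437 in the draws, a difference of 0.0901. With the WT libraries split so that each contrast had its own pair, a median of 13 genes (9 to 21 over 6 ways) were shared, r was 0.35 (0.239 to 0.503) and the covariance 0.0952 (0.0709 to 0.122). The count of 62 became 177 by DESeq2, 272 with library weights, and 25, 24, 24, 35, 33, 33, 21 and 32 without WT 26, WT 27, WT 28, KO 30, KO 31, KO 32, WT_star 20 or WT_star 21.

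**Figure D1:**
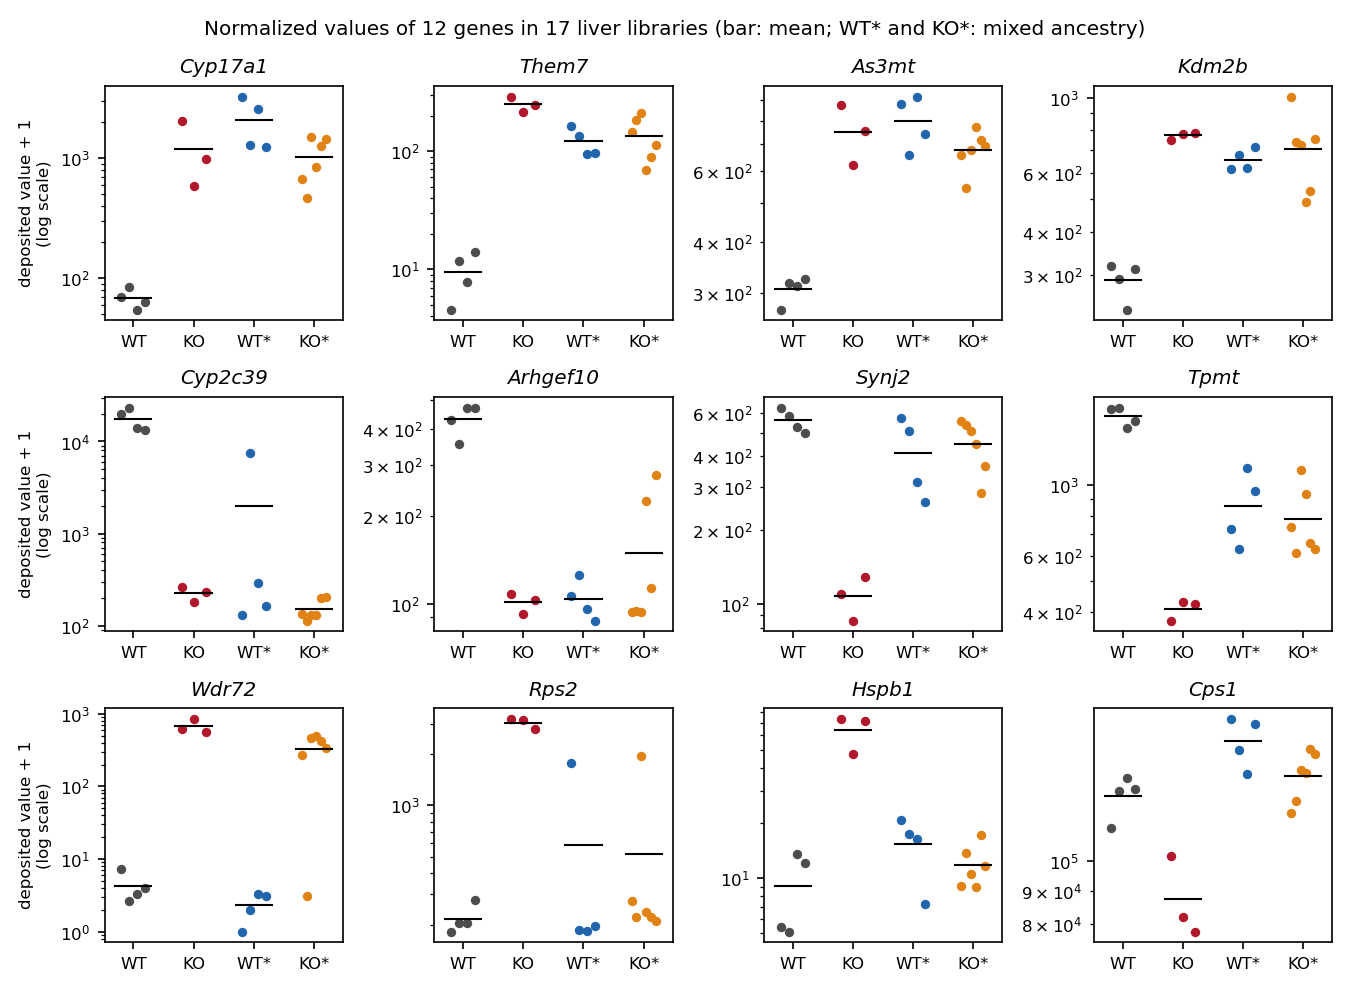
Deposited normalized value plus 1, on a log axis, of 12 genes in each of the 17 libraries, with WT* and KO* standing for WT_star and KO_star and a bar for the group mean. Cyp17a1, Them7, As3mt and Kdm2b were higher in every KO and WT_star library than in every WT library, and Wdr72 was at 2.112 in KO_star 13 while the other KO_star libraries were at 268.6 to 487.4.

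KO_star against WT_star asks for the effect of the Khdc3 genotype among mice of similar mixed ancestry. No gene passed the threshold with limma, where the smallest adjusted p was 0.125 and 1185 genes had an unadjusted p under 0.05. By edgeR 0 genes passed and by DESeq2 62, and 13 passed with library weights. Wdr72 was at 330.2 ± 179.8 (SD, n = 6) in KO_star and 1.345 ± 1.08 (n = 4) in WT_star (log2 fold change 6.36, SE 1.15, adjusted p = 0.14), and library KO_star 13 was at 2.112 while the other KO_star libraries were at 268.6 to 487.4. Without KO_star 13, 20 genes passed, without WT_star 33 6 and without KO_star 12 1. The other genes with the smallest p, each with an adjusted p of 0.14 and no overlap between the groups, were the ubiquitin ligase gene Smurf1 (0.46), the glycerate kinase gene Glyctk (-0.47), the potassium channel gene Kcnn1 (-0.56) and Acat3 (-0.37). Wdr72 and these genes passed by DESeq2 (adjusted p up to 0.00083) and with library weights (up to 0.044), but none of them by edgeR (up to 0.15). Libraries did not overlap for 223 genes, 1.4% of those tested, where chance gives 0.95%. The fold changes of KO against WT and of this contrast, which share no libraries, correlated across genes with r = -0.103 (draws -0.323 to 0.322), their covariance was -0.0164 against 0.0014 in the draws, and 215 of the 467 genes (46%) had the same sign in both. No gene was changed in both by limma, 12 were by DESeq2, 6 with library weights, and 13, 2 and 1 without KO_star 13, WT_star 33 or KO_star 12.

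Camera called 10 lists in KO_star against WT_star, none of them with a changed member over all genes by limma, none with an estimated correlation and none by the directional test of fry, while the mixed test of fry called 3. Bile acid synthesis and transport (median -0.15 over 22, adjusted p = 0.00479, and 0.731 with an estimated correlation) and urea cycle and amino acid breakdown (-0.15 over 26, adjusted p = 0.00155, and 0.731 with an estimated correlation) were lower and kept their calls without each library, with 3 members (Abcb11, Nr0b2 and Slc51b) and 1 member (Slc25a15) lower adjusted over the list alone. The remaining 8 lists had 0 members changed adjusted over the list alone. Acute phase response (-0.22, adjusted p = 0.00195, and 0.731 with an estimated correlation) was lower and was not called without WT_star 33 (0.755), and heat shock response (-0.28, adjusted p = 0.00463, and 0.731 with an estimated correlation) not without WT_star 20 (0.0954). Cell proliferation (0.36, adjusted p = 0.00287, and 0.894 with an estimated correlation) was higher and not called without KO_star 16 (0.776), whose mean level was 8.095 against 5.489 to 6.617 in the other KO_star libraries. Cholesterol synthesis (0.24, adjusted p = 0.00155, and 0.809 with an estimated correlation) was not called without WT_star 33 or KO_star 16 (up to 0.279), and fatty acid synthesis (0.13, adjusted p = 0.00534, and 0.731 with an estimated correlation) not without WT_star 33 (0.129). Fatty acid oxidation (0.10, adjusted p = 0.00463, and 0.894 with an estimated correlation) was not called without WT_star 33, WT_star 34, KO_star 12 or KO_star 13 (up to 0.781). The P450 and conjugation list (0.21, adjusted p = 0.00534, and 0.731 with an estimated correlation) was not called without WT_star 33 or KO_star 13 (up to 0.267), and immediate early genes (0.25, adjusted p = 0.00479, and 0.731 with an estimated correlation) not without WT_star 21, KO_star 13 or KO_star 16 (up to 0.0774).

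KO_star against KO compares genetically KO mice of mixed and of pure KO ancestry. By camera, KO_star livers had lower RNA of fatty acid oxidation, lipid droplet and heat shock genes and higher RNA of urea cycle, DNA methylation enzyme and cell division genes. No list was called with an estimated correlation (smallest adjusted p = 0.241), and no lipid droplet or cell division gene passed by the adjustment over all genes. The urea cycle gene Cps1 rose from 87270 ± 12780 (SD, n = 3) in KO to 134800 ± 11930 (n = 6) in KO_star, with an adjusted p of 0.0079. In KO_star, 236 genes changed, 160 higher and 76 lower, and 2863 had an unadjusted p under 0.05. Of these, 126 had changed in the opposite direction in KO against WT and 0 in the same direction by limma, where independent lists would share 3.52 in opposite directions and the draws shared 0.02 on average (at most 2) with a median of 0 genes called. Without KO 30, KO 31 or KO 32, only 59, 31 and 46 genes were higher in KO_star than in KO, and 7, 6 and 9 lower. The count of 126 therefore depends on each KO library. Both contrasts share the KO libraries. Their r across genes was -0.683 (draws -0.577 on average, -0.792 to -0.165), and their covariance was -0.1658 against -0.0556 in the draws, a difference of -0.1101.

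The lectin-like gene Clec2h (4.89), the acetylcholine receptor gene Chrna4 (2.63), the fetal RNA-binding gene Igf2bp3 (2.51), Adgrf1 (2.41) and the calcium channel gene Cacna1a (2.34) rose with adjusted p of 0.013, 0.018, 0.00064, 0.042 and 0.0088. Synj2, which had fallen in KO, rose from 107 ± 21.8 (SD, n = 3) to 448.9 ± 107.1 (n = 6), with an adjusted p of 0.00047. The carboxylesterase gene Ces1b (2.04), the meiotic recombination genes Meiob (1.95) and Msh5 (1.92) and the lipid phosphatase gene Mtmr7 (1.91) rose with adjusted p of 0.013, 8.3e-05, 0.022 and 0.00025. Serpina12 (-2.54), the spliceosomal RNA gene Rnu12 (-1.86) and Hapln4 (-1.83) fell with adjusted p of 0.048, 0.039 and 0.021. Fam131c fell from 252.2 ± 23.7 (n = 3) to 63.56 ± 15.2 (n = 6), with an adjusted p of 0.019. Tedc2 (-1.42), Rfxank (-1.37), B3gnt3 (-1.37), the non-coding Lncbate6 (-1.22) and the proton pump gene Atp6v0c (-1.19) fell with adjusted p of 0.0093, 0.0088, 0.017, 0.036 and 0.019. Hapln4, Rfxank and B3gnt3 lie within 1.61 Mb on chromosome 8, from 70083457, and Tedc2 and Atp6v0c on chromosome 17 at 24215054 and 24163866. The libraries did not overlap for 1798 genes, 11.1% of those tested, where chance gives 2.38%. They did not overlap for every gene named in this contrast except Rplp1, as the naming rule required of the genes with the largest change.

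Camera called 14 lists in KO_star against KO, 11 higher and 3 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.241, and fry called 5 by its directional and 14 by its mixed test. Fatty acid oxidation and ketogenesis had a median of -0.41 over 34 (adjusted p = 9.68e-11, and 0.538 with an estimated correlation), with 1 member lower over all genes and 14 adjusted over the list alone. Lipid droplets had a median of -0.61 over 14 (adjusted p = 8.68e-05, and 0.257 with an estimated correlation), with 0 members over all genes by limma and 8 lower adjusted over the list alone. Heat shock response had a median of -0.48 over 14 (adjusted p = 2.26e-06, and 0.428 with an estimated correlation), with Hspb1 lower over all genes (-2.45, adjusted p = 0.0038) and 9 members adjusted over the list alone. Urea cycle and amino acid breakdown had a median of 0.24 over 26 (adjusted p = 9.76e-08, and 0.241 with an estimated correlation), with Cps1, Agxt (0.66) and the glutaminase gene Gls2 (0.60) higher over all genes and 8 members adjusted over the list alone. DNA methylation enzymes had a median of 0.45 over 10 (adjusted p = 0.00175, and 0.241 with an estimated correlation), with Dnmt3a (0.60, adjusted p = 0.013) and Tet3 (0.58, adjusted p = 0.04) higher by both adjustments. Library KO_star 16 stood highest in this list at 8.85, against 8.135 to 8.261 in the other KO_star libraries, and the list was called without each library. Cell proliferation had a median of 1.13 over 29 (adjusted p = 9.68e-11, and 0.538 with an estimated correlation), with 0 changed members by limma in either adjustment, and was called without KO_star 16 as well as without each other library. Methionine and one-carbon metabolism (0.22, adjusted p = 0.00241, and 0.241 with an estimated correlation) had 0 changed members by either adjustment, and neutrophil and monocyte markers (0.74, adjusted p = 0.0131, and 0.538 with an estimated correlation) had Ngp higher adjusted over the list alone.

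Of the remaining 6 lists, periportal hepatocyte markers (0.25, adjusted p = 0.015, and 0.241 with an estimated correlation), with Aldh1b1 (0.52, adjusted p = 0.039) and Gls2 higher and 3 members adjusted over the list alone, were not called without KO 30 (0.0527). Cytosolic ribosomal proteins (0.09, adjusted p = 0.00129, and 0.783 with an estimated correlation), with Rplp1 higher (0.78, adjusted p = 0.039) and 2 members higher and 1 lower adjusted over the list alone, were not called without KO 32 (0.0629). Kupffer cell and macrophage markers (0.35, adjusted p = 0.00816, and 0.783 with an estimated correlation) were not called without KO 32 or KO_star 13 (up to 0.0811), and cholesterol synthesis (0.15, adjusted p = 0.015, and 0.808 with an estimated correlation) not without KO 31 or KO_star 16 (up to 0.301). Nuclear oxidative phosphorylation (0.05, adjusted p = 0.0352, and 0.808 with an estimated correlation) was not called without KO 32, KO_star 12, KO_star 13 or KO_star 14 (up to 0.148), and immediate early genes (0.43, adjusted p = 0.0437, and 0.717 with an estimated correlation) not without KO 30, KO 32, KO_star 12, KO_star 13 or KO_star 16 (up to 0.131). The last 4 lists had 0 changed members over all genes by limma, and 1 immediate early gene, Ier2, was higher adjusted over the list alone. The number of changed genes was 208 by edgeR, 814 by DESeq2, 850 with library weights and 371 with equal library totals, of which 154 were higher and 217 lower, and 66, 37, 55, 136 and 157 without KO 30, KO 31, KO 32, KO_star 16 or KO_star 29. Igf2bp3, Synj2, Meiob, Mtmr7 and Hspb1 kept their call in every alternative in which they were tested, and each other gene named lost it in at least 1, with adjusted p of up to 0.21.

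**Figure D2:**
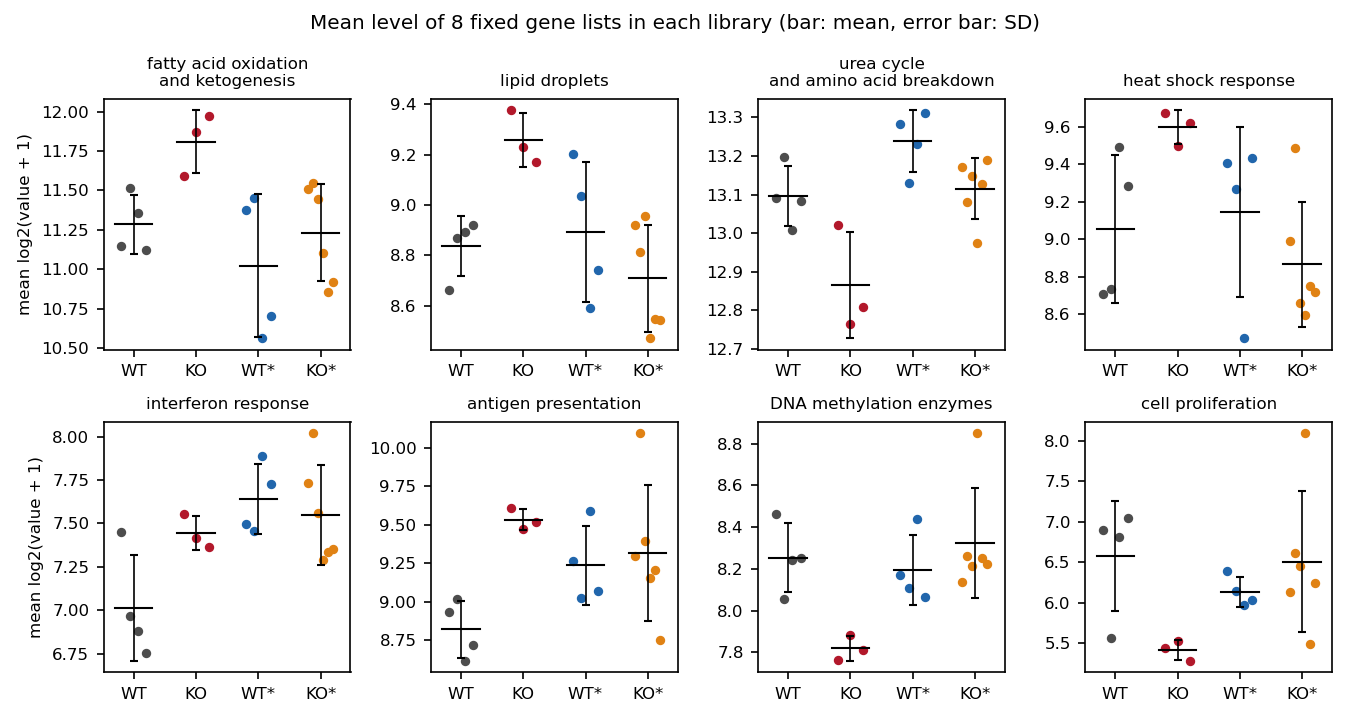
Mean log2(value + 1) of the tested members of 8 gene lists in each of the 17 libraries, with the group mean as a bar and the SD as an error bar. The 3 KO libraries lay above every WT library for fatty acid oxidation, and below every WT library for DNA methylation enzymes, at 7.762 to 7.882 against 8.056 to 8.462.

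KO_star differed from WT at 114 genes, 75 higher and 39 lower, with 1958 at an unadjusted p under 0.05. This count was 112 by edgeR, 341 by DESeq2, 201 with library weights, 68 with only these libraries, and 51, 51, 54 and 67 without WT 26, WT 27, WT 28 or KO_star 17. The interaction of genotype and ancestry passed at 209 genes, 122 positive and 87 negative, with 2575 at an unadjusted p under 0.05. It contains KO minus WT with a minus sign, so a gene or list chosen for a large difference between KO and WT gets the opposite sign in part by construction. Among the named genes it passed for Cyp17a1 (-4.97, adjusted p = 0.0014), Them7 (-4.73, adjusted p = 0.00014), Hspb1 (-3.25, adjusted p = 0.0058), Col4a3 (5.75, adjusted p = 0.012) and Synj2 (2.54, adjusted p = 0.0014). It did not pass for Wdr72 (-1.02, adjusted p = 0.83), Pctp (-3.31, adjusted p = 0.26), Tiam2 (-5.16, adjusted p = 0.057), H2-Eb1 (-3.95, adjusted p = 0.17), Rps2 (-3.83, adjusted p = 0.11), Cdcp1 (-2.69, adjusted p = 0.097) and Csad (-2.95, adjusted p = 0.11). Camera called 12 of the 40 lists for the interaction, 6 positive and 6 negative, and none with an estimated correlation. Among these the interaction was negative for interferon response (median -0.43, adjusted p = 1.02e-05, and 0.74 with an estimated correlation), heat shock (-0.66, adjusted p = 3.51e-05, and 0.74 with an estimated correlation) and lipid droplets (-0.51, adjusted p = 0.00206, and 0.74 with an estimated correlation). It was positive for cell proliferation (1.57, adjusted p = 3.32e-11, and 0.74 with an estimated correlation) and DNA methylation enzymes (0.46, adjusted p = 0.0083, and 0.74 with an estimated correlation). In KO_star against WT_star, a part of the interaction, camera did not call proliferation without KO_star 16 (adjusted p = 0.776). The interaction count was 207 by edgeR, 695 by DESeq2 and 866 with library weights, with 79 positive and 153 negative genes at equal library totals. Without WT 25, WT 28, KO 30, KO 31, KO 32, WT_star 20, WT_star 21 or WT_star 33 it was 137, 114, 74, 83, 81, 77, 123 and 498.

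Genes changed in KO against WT lay closer together on the chromosomes than matched sets of genes. The segments named here were picked as the densest in changed genes, so their counts are high by choice and are no test. Over all 16157 genes tested, 467 changed in KO against WT, 146 in WT_star against WT and 236 in KO_star against KO. On chromosome 8, between 68793929 and 72460489, 20 of 115 tested genes changed in KO against WT, among them Lpl, Hapln4, Rfxank and B3gnt3. On chromosome 17, between 21650624 and 25188397, 17 of 119 changed, among them Rps2, Atp6v0c, Tedc2 and Meiob, and between 30584936 and 35470089 11 of 145 changed, among them H2-K1, H2-Eb1, H2-Q1 and H2-Q10. In WT_star against WT, 6 of 69 tested genes changed on chromosome 19 between 42036000 and 46707458, all higher, among them Loxl4, Cyp17a1 and As3mt. Of the genes changed in KO against WT, 73.2% had another within 2 Mb, against 63.9% in matched sets (permutation p = 2e-04, one-sided). For the 62 genes shared with WT_star the share was 51.6%, against 15% in matched sets (permutation p = 1e-04, the smallest that 10000 draws can give). It was 39% against 31% in WT_star against WT (permutation p = 0.057) and 42.8% against 43.6% in KO_star against KO (permutation p = 0.6). In simulated sets with part of the genes placed in segments, this test called 44%, so the last value does not exclude segments. In KO_star against KO, 17 of 115 tested genes changed on the same segment of chromosome 8, and 10 of 119 on chromosome 17 between 21650624 and 25133391. The lists of Khdc3 chromosomal neighbours and of genes that differ between inbred strains, with adjusted p of 0.667 and 0.921 in KO against WT by camera, held 1 changed member each, Elovl5 and Glo1, both higher.

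**Figure D3:**
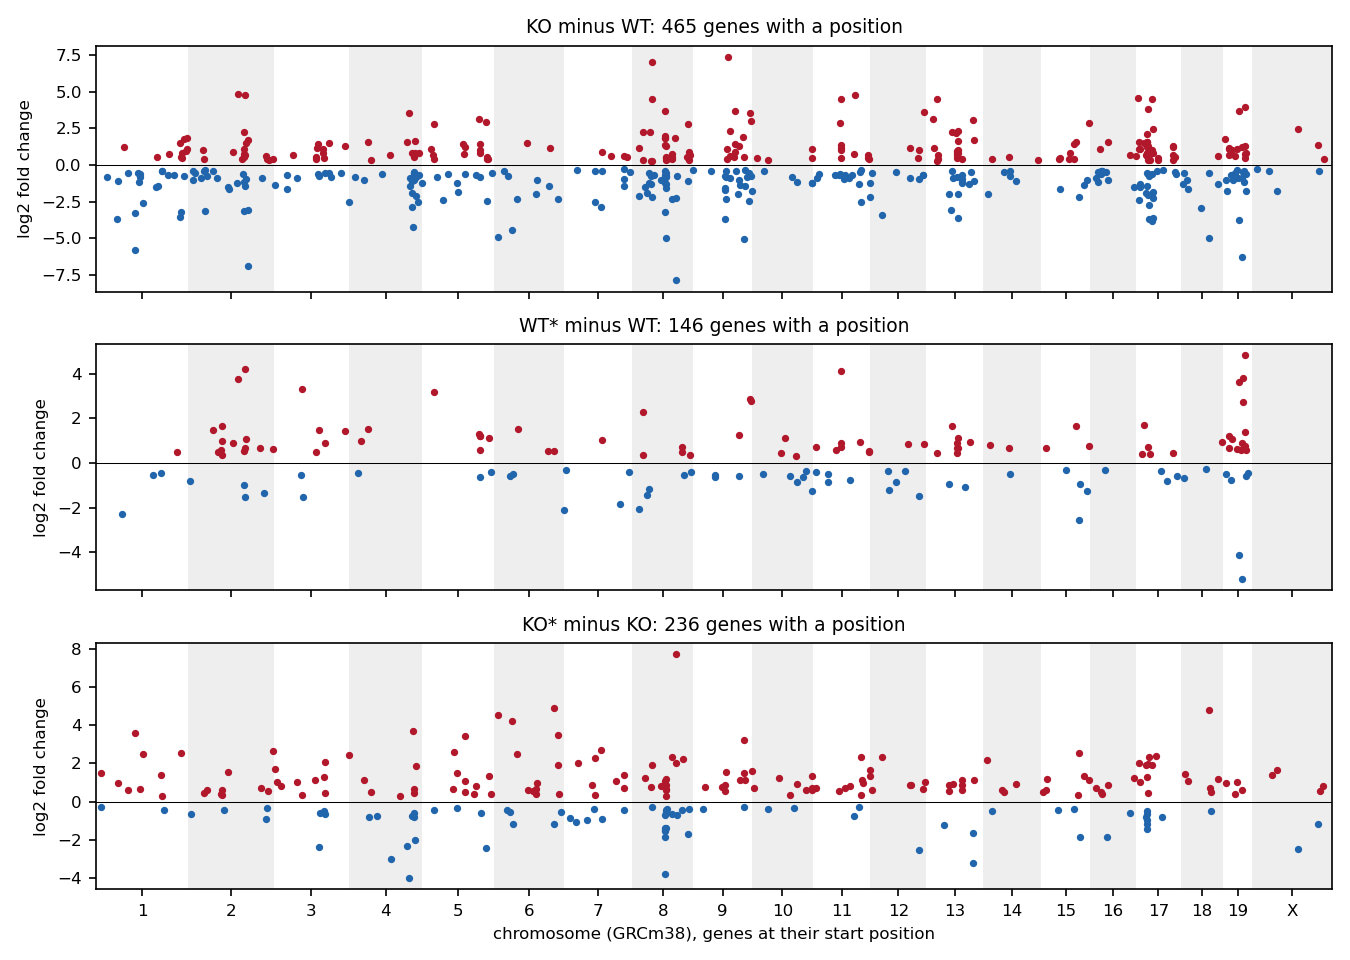
Log2 fold change of each changed gene against its start position along the chromosomes (GRCm38), for KO minus WT, WT* minus WT and KO* minus KO, with higher genes in red, lower genes in blue and chromosomes in alternating shades. Changed genes of both directions stand in columns on chromosomes 8 and 17 in the KO panel, where 20 of 115 and 17 of 119 tested genes of a segment changed.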

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

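The tests of DNA linked to the Khdc3 allele, of the nearest genes of Khdc3 alone, and of every explanation for library KO_star 16 were chosen only after the result was seen. The pairwise test of inherited DNA segments, the tests of paralogs and of local co-regulation, the reading of KO_star 13 and the splits of the samples had their predictions written first.

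Genes changed in KO against WT lay close together on the chromosomes. Reads shared between paralogs or pseudogenes of 1 symbol root, the letters before the first digit or hyphen, do not account for this. Of the changed genes, 70.6% (329 of 466) had a neighbour of a different symbol root within 2 Mb, against 62.7% in matched sets (upper bound 67.6%, permutation p = 8e-04). A copy under another name counts as a different root. As 73 of the 467 changed genes were predicted genes, named pseudogenes or without a symbol, reads shared with such copies are left open. Local co-regulation that moves neighbours the same way does not account for the pairs changed in opposite directions. These were negatively correlated across the 10 star libraries (-0.314 over 563 pairs, shuffles -0.116 to -0.045). Local regulation with opposite effects on neighbours would also give a negative value, so the test does not decide about it. Nor does it decide about the 597 pairs changed in the same direction, whose correlation of 0.282 (shuffles 0.052 to 0.126) co-regulation could also give. Inherited DNA segments that differ between the KO and WT lineages fit, as near changed genes moved together in the star libraries with a mean sign-aligned correlation of 0.297 over 1160 pairs (shuffles 0.056 to 0.113). An inherited mark that stays on its chromosome segment, which the mixed ancestry of the star groups leaves open, would give the same value of 0.297 and was not tested, since no DNA sequence was analysed here.

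Genes near Khdc3 differed between KO_star and WT_star more often than elsewhere. Within 20 Mb, 15.4% of genes (43 of 280) had an unadjusted p under 0.05, against 7.1% on average in 1033 windows elsewhere (upper bound 11.8%), 11 of which were as high, which fits DNA linked to the Khdc3 allele. An effect of the deletion on genes within 2 Mb alone would not raise the share between 2 and 20 Mb, which was 16.2% (38 of 234, windows up to an upper bound of 12.3%). This argues against it but does not exclude it, as 9 of 1127 windows elsewhere were as high and no gene passed the threshold by limma. Library KO_star 13 stood at a median of 10.9% between the WT and KO means over 17 changed genes of this flank without Wdr72, against 40.3% to 74.8% in the other KO_star libraries and 22.4% to 33.3% in WT_star, which fits a library that does not carry the KO form of the region. KO_star 13 stood at -2% for Aph1c on 1 side of Khdc3, and at -4.9% for Wdr72 and -17.3% for 9430037G07Rik on the other. Bnip2 (65.3%) and Elovl5 (85.2%), also on opposite sides, went the other way. A recombination on 1 side alone would leave the other side KO-like, so recombination would have to lie on both sides to give the low values. A wrong genotype label and such recombinations were not separated, so the KO_star comparisons hold 1 library whose genotype the data do not bear out.

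Library KO_star 16 stood apart, with 93 genes above 2 times every other library and 22640 genes with reads, against 21480 to 21860 in the other KO_star libraries. Depth does not account for this, as WT 26, the 1 library with more reads, had 7 such genes. Pancreas in the sample fits the acinar genes, as 12 of 12 had their most reads there, 6600 together, with Cpb1 at 1035 reads against 1 or 0 elsewhere. Whether it also brought the H19 reads cannot be told apart, as H19 was at 17510 (288.8 or less elsewhere) and the acinar genes summed to 5230, but no table holds the profile of the tissue mixed in. The closest library to KO_star 16 was KO_star 12 (r = 0.235 across genes), of its own group. This does not decide whether the sample came from another group, as WT_star 33 and WT_star 34 were closest to KO_star 17 (0.163) and KO_star 29 (0.088). No biological explanation was tested.

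In groups of 4 to 6 libraries, 25 of 417 tested sets had 1 library far from the others, where chance gives about 1 in 20 groups (5%). Among single genes these included Adgrf1 in KO_star 29 (139.5, others 447.2 to 789.3), Atp6v0c in WT_star 20 (455.1, others 208.3 to 221.3), Cd36 in WT_star 33 (668.1, others 388.8 to 417.7), Clec2h in WT_star 20 (12.54, others 100 to 149.4) and H2-Q10 in WT 28 (18250, others 16590 to 16660). Further genes were Lncbate6 in WT_star 34 (48.47, others 69.87 to 75.28), Loxl4 in WT_star 21 (196.2, others 511.6 to 610.6), Neb in WT_star 33 (2546, others 1390 to 1482), Pdgfrb in WT 26 (404.1, others 511.7 to 535.3) and Rplp1 in WT 28 (3440, others 2747 to 2835). Wdr72 was at 2.112 in KO_star 13 (others 268.6 to 487.4), and Rps2 stood out in WT_star 20 (1775, others 183.5 to 194.9) and KO_star 14 (1938, others 209.3 to 273.6).

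Among mean levels of lists on the log2 scale, the growth hormone and insulin axis stood apart in WT_star 20 (11.05, others 11.15 to 11.17), P450 and conjugation genes in KO_star 17 (11.63, others 11.93 to 12.08), immediate early genes in WT 28 (7.334, others 7.553 to 7.587) and cell proliferation in WT 26 (5.567, others 6.809 to 7.047). DNA methylation enzymes (8.85, others 8.135 to 8.261) and imprinted genes (8.161, others 6.944 to 7.326) were high in KO_star 16. T and NK cell markers were low in WT 27 (3.397, others 3.921 to 3.983), cholangiocyte markers low in KO_star 14 (5.126, others 5.731 to 5.914) and Khdc3 chromosomal neighbours high in KO_star 13 (9.14, others 8.89 to 8.947). Ribosomal protein genes took 0.57% of the reads in WT 28 (others 0.51% to 0.52%).

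For 31 of the 93 named genes the interaction test passed the threshold, given here as log2 differences. Over all genes it passed at 209 of 16157. The named genes were chosen for large differences in contrasts that the interaction contains, KO minus WT and WT_star minus WT with a minus sign and KO_star minus WT_star and KO_star minus KO with a plus sign, so both its sign and the share of 31 of 93 come in part by construction. Negative values, where KO_star minus WT_star lay below KO minus WT, were found for Cyp17a1 (-4.97), Them7 (-4.73), Hspb1 (-3.25), AI506816 (-3.14), G0s2 (-2.73), Hapln4 (-2.71), Rfxank (-1.98), B3gnt3 (-1.83), Igkc (-1.74), As3mt (-1.52), Spsb4 (-1.49), Atp6v0c (-1.43), Kdm2b (-1.36), H2-K1 (-1.12), Ift81 (-1.12) and Stat2 (-0.63). Positive values were found for Col4a3 (5.75), Col4a4 (3.08), Cacna1a (2.91), Ces1b (2.91), Synj2 (2.54), Arhgef10 (2.47), Fut10 (2.45), Igf2bp3 (2.36), Mtmr7 (2.35), Meiob (2.23), Tpmt (1.85), Slc38a2 (1.71), Abcg5 (0.96), Dnmt3a (0.84) and Smurf1 (0.82).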

How the results depend on the processing

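Leaving out KO_star 16 from KO against WT and from WT_star against WT was chosen only after the result was seen and gave 617 and 150 changed genes. No named gene changed direction, but equal totals turned the balance of higher and lower genes from 213 and 254 to 338 and 188 for KO against WT, from 160 and 76 to 154 and 217 for KO_star against KO, and from 122 and 87 to 79 and 153 for the interaction. Of 1097 values of named genes under other settings, 1015 kept their direction and side of the threshold, 72 lost it and 10 gained it. Of 870 values with a library left out, 490 kept it, 376 lost it and 4 gained it. With DESeq2 the changed genes numbered 865 for KO against WT, 602 for WT_star against WT, 62 for KO_star against WT_star, 814 for KO_star against KO, 341 for KO_star against WT and 695 for the interaction. With library weights they numbered 1280, 757, 13, 850, 201 and 866 in the same order, and the cause was not tested. With only the groups compared, the spread is estimated from fewer libraries and without those of the other groups. The changed genes then numbered 754 for KO against WT, up from 467, 96 for WT_star against WT, down from 146, and 68 for KO_star against WT, down from 114. The cause of the rise was not tested. An absolute log2 fold change of at least 1 left 229, 50, 104, 51 and 123 genes for KO against WT, WT_star against WT, KO_star against KO, KO_star against WT and the interaction, and equal totals gave 371 for KO_star against KO, cause not tested. Genes changed the same way in KO and WT_star against WT numbered 177 with DESeq2, 272 with library weights and 13 with the WT libraries split 2 and 2, where fewer libraries enter and r was 0.35. Genes shared by KO against WT and KO_star against WT_star numbered 12 with DESeq2 and 6 with library weights. Lists called fell to 0 in all 4 contrasts with an estimated correlation, and with the directional test of fry to 0, 0, 0 and 5, while its mixed test called 17, 9, 3 and 14. Leaving out 1 library at a time, which lowers n, gave 150 to 617 changed genes for KO against WT, 33 to 184 for WT_star against WT, 0 to 20 for KO_star against WT_star, 37 to 259 for KO_star against KO, 51 to 134 for KO_star against WT and 74 to 498 for the interaction. The genes shared by KO and WT_star numbered 21 to 68 (r 0.525 to 0.611), those shared by KO against WT and KO_star against WT_star 0 to 13 (r -0.157 to -0.014), and lists called 12 to 20, 4 to 13, 7 to 14 and 10 to 17. Pseudocounts, filters, quantile normalization and edgeR kept every count of changed genes within 1.5 times. No paired analysis was possible because the groups share no replicate numbers. At 17.62 to 26.7 M reads, Khdc3 at 0 to 4 reads per library lies below what can be compared between genotypes.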

Other observations

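The values of single libraries in this part were chosen only after the result was seen, and the splits of the samples were planned. Some liver programs varied between libraries of the same group. The acute phase response, the secreted proteins that liver makes in inflammation, had its highest mean level in WT_star 33 (13.999 on the log2 scale) and WT_star 34 (12.718), against 11.502 and 11.529 in the other WT_star libraries and 11.318 to 12.242 in the other groups. The same 2 libraries had the lowest levels of fatty acid oxidation genes, 10.563 and 10.707 against 10.857 to 11.972 elsewhere. Female-biased liver genes were at 11.304 and 11.211 in WT 25 and WT 26 and at 10.306 and 10.23 in WT 27 and WT 28, where male-biased genes were at 8.99 and 9.081 against 7.987 and 8.325. Male-biased genes were lowest in KO_star 16, at 7.338. Across genes, after the mean of the 4 group means was subtracted from each gene, WT 27 correlated best with WT 28 (r = 0.56), KO 31 with KO 32 (0.442), WT_star 20 with WT_star 21 (0.42), WT 25 with WT 26 (0.349) and KO_star 17 with KO_star 29 (0.311). WT_star 33 correlated best with KO_star 17 (0.163, best in its own group 0.074) and WT_star 34 with KO_star 29 (0.088, best in its own group 0.074).

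Among the 93 genes of KO_star 16 above 2 times every other library were some fetal and muscle genes, and no list of such genes was tested. Igf2 was at 187 (19.4 or less elsewhere), Afp at 127.6 (45.87 or less), the titin gene Ttn at 784.6 (36.46 or less) and the muscle myosin light chain gene Mylpf at 307.5 (15.98 or less). All 29 tested cell division genes were highest in this library.

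Star libraries took different positions between the WT mean (0%) and the KO mean (100%) over the changed genes of the 5 segments densest in genes changed in KO against WT. Over 20 genes on chromosome 8 between 68793929 and 72460489, WT_star 20 stood at 44.5%, WT_star 21 at 48.3% and KO_star 12 at 26.8%, and the other star libraries at 1.7% to 13%. Over 17 genes on chromosome 17 between 21650624 and 25188397, WT_star 20 stood at 55.1% and KO_star 14 at 44.5%, and the others at -0.4% to 18.5%. Over 12 genes on chromosome 13 between 63410918 and 67831106, WT_star 33 stood at 53.8%, WT_star 34 at 47.7% and KO_star 14 at 30.4%, and the others at 79.2% to 97.6%. Over 11 genes on chromosome 17 between 30584936 and 35470089, WT_star 20, WT_star 21, KO_star 13 and KO_star 14 stood at 80.9% to 89.3%, and the others at 5.5% to 43.5%. Over 11 genes on chromosome 2 between 117121374 and 122028546, WT_star 20, WT_star 21, KO_star 12, KO_star 13 and KO_star 14 stood at 88.9% to 101.5%, and the others at 30.5% to 54%. Rps2, on the first of the chromosome 17 segments, was at 1775 in WT_star 20 and 1938 in KO_star 14, where the middle between the WT and KO means is 1630.

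The libraries of each contrast were regrouped with the group sizes kept. The 467 genes of KO against WT were reached by 1 of 35 splits, the real one, with at most 4 in the others, and the 146 of WT_star against WT by 1 of 35, with at most 4. The 236 of KO_star against KO were reached by 1 of 84, with at most 24, and the 114 of KO_star against WT by 1 of 100 drawn from 210, with at most 29. The interaction count of 209 was reached by 2 of 100 drawn from 7350, with up to 511 in another. For KO_star against WT_star the real count was 0, which all 100 of 100 splits reach whatever the data, so the splits decide nothing about that grouping. The highest of the 100, WT_star 20, 21 and 34 with KO_star 13, 17 and 29 against the rest, gave 357 (median 0), which points to a structure of the samples, and what these libraries share was not tested.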
